A study of Mus musculus with 14 samples.

How the data were processed

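Liver tissue free of tumour from female mice aged 14 months was profiled, with 3 wild-type, 5 Mdr2-KO and 6 Mdr2-KO/IL6-KO arrays as the labels group them. Per the labels, RNA was extracted with Trizol from snap-frozen tissue and treated with DNase, and biotinylated cRNA was hybridised to an Affymetrix mouse gene array. The deposited table holds log2 values, which per the labels were made by the authors with Partek and RMA, a method that corrects background, normalises quantiles between arrays and summarises probes. The versions of both tools, the genome build behind the probes, any filter and any pooling of samples are not given in the sources used here. All values lie between 1.47 and 13.60, a range that fits the log2 scale. No batch or scan date is in the labels, so no batch could be set against the groups. No 2 arrays were identical, and at most 0.062% of values were equal between any pair.

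The table has 35557 probes. The array annotation names 23410 of them, 21789 with 1 gene and 1621 with several genes, and 12147 have no gene name. Of the probes with 1 gene, 21698 were matched through their gene identifier. Each gene was represented by its probe of highest mean, which mattered for the 999 genes with more than 1 probe, and 19938 genes were tested with no filter on dim genes. The authors' normalization was kept.

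Genes were tested in limma 3.58.1 under R 4.3.3 with a model of 3 group means over the 14 arrays, empirical Bayes moderation, a 2-sided moderated test and Benjamini-Hochberg adjustment over all genes tested, at an adjusted p of 0.05. Python 3.11.15 read the tables and matplotlib 3.10.9 drew the plots. A set of 46 gene lists with 781 members, of which 701 were measured, was tested with camera at a preset correlation between genes of 0.01, adjusted over the 46 lists within each comparison. Camera asks whether a list moved more than the other genes, and its estimated correlation replaces the preset value with 1 measured per list. The directional test of fry asks whether a list's genes move on balance in 1 direction, and compares the list with no other genes. The comparisons, tests, thresholds, lists, the rule for named genes and the first set of alternative settings were fixed before the data were examined.

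The rule named Abcb4 and Il6 in every group. It named, per comparison, the 10 largest rises and the 10 largest falls among genes past the threshold whose arrays do not overlap between the groups, with predicted gene models counted but not named. Per list and comparison it allowed up to 4 members past the threshold with the largest change or, where none passed, the largest as a value. The text shows a part of these, choosing among the 4 mostly members whose call stayed when any 1 array was left out. The members named because they went against their list (Adam12, Gclm, Uqcrc2, Acadvl, Rps20, Rpl6 and Rpl4), and the values of Phf5a, S100a10 and Alyref against wild type, were chosen after they were seen. A background level was also chosen after the data were seen, as the value under which 95% of 1015 olfactory receptor genes lie (5.49), and 29.2% of the genes tested have a mean under it. Precision rests on 3, 5 and 6 arrays per group and on signal over this background.

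The procedure was tested on simulated data with the same group sizes, 19938 genes and seeded changes. Of changes of 0.5 log2 units it recovered 77.6% for Mdr2-KO against wild type, 76.1% for Mdr2-KO/IL6-KO against wild type and 88.1% between the knockouts, and of changes of 1 log2 unit 92.5%, 98.5% and 98.5%. False calls numbered 16, 14 and 8, and all 5 seeded lists were found in each comparison. The simulated genes were drawn independently of each other, whereas genes of the real lists move together, with an estimated correlation of 0.525 for acute phase proteins. The simulation therefore cannot show how the preset correlation of camera performs on the real lists. The correlation of fold changes that share the wild-type arrays was set beside 100 simulations of unchanged groups.

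The alternatives were quantile normalization of the deposited values, centring of each array on its median, leaving out the genes of lowest mean value so that 13292 remained, the mean of a gene's probes, all 35557 probes, moderation with trend and robust settings, array quality weights, only the 2 groups compared, a fold change of at least 1.5, correlation estimated per list, fry, and each array left out in turn. Added after the data were seen were leaving out wild-type array 2 and Mdr2-KO array 3 together, leaving out Mdr2-KO array 3 and Mdr2-KO/IL6-KO array 2 together, and leaving out 70 small noncoding RNA genes. Probes with several gene names or none were left out of gene tests because their signal cannot be given to 1 gene. Positions near the targeted genes were taken from GRCm38.p6.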

Results

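Gene expression was measured in liver tissue free of tumour from female mice aged 14 months, which were wild type (C57BL/6), lacked Mdr2 (Mdr2-KO) or lacked Mdr2 and IL6 (Mdr2-KO/IL6-KO). The strain background and the number of backcrosses of the knockouts were not known here. A strain difference can therefore not be told apart from loss of the targeted genes. There were 14 arrays, 3 from wild type, 5 from Mdr2-KO and 6 from Mdr2-KO/IL6-KO, each an Affymetrix mouse gene array hybridised with biotinylated cRNA made from total RNA. Mdr2 is the older name of Abcb4, the canalicular transporter that puts phosphatidylcholine into bile, and mice without it are a model of chronic bile duct injury with later liver tumours. Il6 encodes interleukin 6, the cytokine that drives the acute phase response in hepatocytes. The deposited values are on the log2 scale, 1 value per probe and array, and 19938 genes could be tested. The median value of an array lay between 6.15 and 6.24. The number of arrays limits the precision of every comparison. Means are given with their SD, and differences, in log2 units, with their standard error (SE), n = 3 for wild type, n = 5 for Mdr2-KO and n = 6 for Mdr2-KO/IL6-KO throughout. The labels do not say whether each array comes from a separate mouse, so the p-values measure the spread between these arrays.

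In a principal component analysis the first component held 32.3% of the variance and separated wild type, at -37.9 to -24.2, from all knockout arrays, at 1.24 to 14.1. The second component held 18.3% and separated Mdr2-KO, at -25.9 to -2.26, from Mdr2-KO/IL6-KO, at 5.93 to 17.0. Mdr2-KO array 3 was the lowest of all on the second component, where wild type lay between -7.73 and 4.54. Correlations between arrays of 1 group averaged 0.991 in wild type, 0.992 in Mdr2-KO and 0.993 in Mdr2-KO/IL6-KO, across genes, which are not independent replicates.

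**Figure D1:**
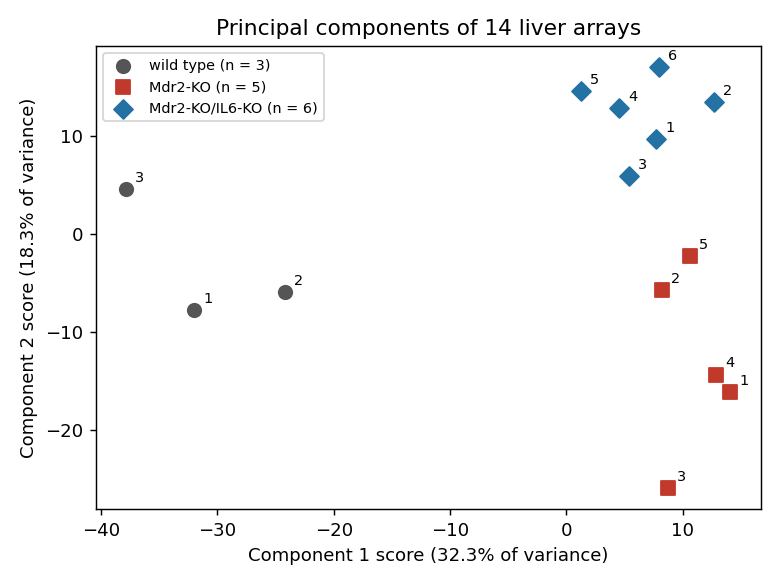
Each point is 1 array, placed by its score on the first (32.3% of the variance) and second (18.3%) principal components of all genes tested. Wild-type arrays lie between -37.9 and -24.2 on the first axis, and the second axis separates Mdr2-KO, at -25.9 to -2.26, from Mdr2-KO/IL6-KO, at 5.93 to 17.0.

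The targeted genes were read first. Abcb4 transcript signal fell from 10.36 ± 0.03 in wild type to 9.01 ± 0.19 in Mdr2-KO (log2 fold change -1.36, SE 0.12, adjusted p = 5.09e-06) and to 9.05 ± 0.20 in Mdr2-KO/IL6-KO (-1.32, SE 0.11, adjusted p = 4.84e-06). Every knockout array lay below every wild-type array, and the knockout groups differed from each other by 0.04 (adjusted p = 0.816). Il6 read 3.22 ± 0.10 in wild type, 3.07 ± 0.15 in Mdr2-KO and 3.48 ± 0.31 in Mdr2-KO/IL6-KO. These Il6 values lie under 5.49, the level under which 95% of 1015 olfactory receptor genes lie and which serves here as the background of the array. The loss of Il6 transcript could therefore not be read from these arrays.

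The comparison of Mdr2-KO with wild type asks what loss of Abcb4 changes in old, tumour-free liver. In Mdr2-KO 8 of 18 markers of bile duct cells, 6 of 26 extracellular matrix genes and 6 of 19 markers of recruited macrophages were higher, and 9 of 11 genes that female mouse liver expresses more than male liver were lower. With an estimated correlation none of these lists passed (adjusted p = 0.383, 0.659, 0.383 and 0.345). Ly6d, a lipid-anchored cell surface protein, rose from 7.12 ± 0.65 to 10.24 ± 0.47 (3.12, SE 0.35, adjusted p = 4.81e-05). Lumican (Lum), a proteoglycan of the collagen matrix, rose from 6.81 ± 0.21 to 8.91 ± 0.43 (2.10, SE 0.22, adjusted p = 2.44e-05). Cyp17a1, a steroid hydroxylase, fell from 11.17 ± 0.64 to 7.35 ± 1.54 (-3.81, SE 0.61, adjusted p = 0.000813). In all, 4189 of the 19938 genes passed the threshold, 1772 higher and 2417 lower, and 799 of them changed at least 1.5-fold, 456 higher and 343 lower. After quantile normalization the split of all that passed was 1793 higher and 1763 lower. Without wild-type array 3 the count was 2140. In 575 of the 4189 genes the signal was under the background in both groups. The median log2 fold change was -0.073 over all genes tested and -0.108 over 1015 olfactory receptor genes. Small falls can therefore not be told apart from a shift shared by many genes of an array.

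Among the largest rises whose arrays did not overlap between the groups were Cib3 (5.78 to 9.05, 3.26, SE 0.25, adjusted p = 2.7e-06), the trefoil peptide Tff3 (6.96 to 9.87, 2.91, SE 0.39, adjusted p = 0.000214) and the cytochrome P450 Cyp2c39 (9.46 to 11.99, 2.53, SE 0.14, adjusted p = 6.5e-08). Mucl2, Cyp4a12a, Cyp4a12b, Folh1 and Elovl7 rose by between 2.36 and 3.40 from a wild-type signal under the background, so these sizes are not exact. The small nucleolar RNA Rnu3a (U3) rose by 2.36 (SE 0.20, adjusted p = 4.31e-06). Among falls without overlap between the groups were those of Cyp17a1, Cyp2b13 (-2.99) and the acyl-CoA thioesterase Acot3 (-2.91), which stayed above the background. The sulfotransferase Sult2a3 (adjusted p = 5.93e-05), Klra17 and Fcrl5 fell from 7.88, 6.88 and 7.62 to a signal under the background, so the sizes of their falls are not exact. Cyp2b13 no longer passed without wild-type array 2 (adjusted p = 0.0602) or array 3 (adjusted p = 0.0693). Near-identical genes such as Cyp4a12a and Cyp4a12b, Saa1 and Saa2, and the Sult and Mup families can share probe signal, so their members are not separate readings.

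Of the 18 measured cholangiocyte and ductular cell markers, 8 rose and the other 10 did not pass (12 rose when adjusted over the list alone; camera adjusted p = 3.94e-08, and adjusted p = 0.383 with an estimated correlation). Tspan8 rose from 4.84 ± 0.50, under the background, to 7.14 ± 0.49 (2.30, SE 0.28, adjusted p = 7.59e-05), Cd24a rose by 1.79 (SE 0.32, adjusted p = 0.00154) and keratin 19 (Krt19), a cytoskeletal marker of bile duct cells, by 1.07 (SE 0.23, adjusted p = 0.00487). Collagens and extracellular matrix genes rose in 6 of 26 and 20 did not pass, with 7 rising when adjusted over the list alone (camera adjusted p = 0.000806, and adjusted p = 0.659 with an estimated correlation). Lumican led this list, and dermatopontin (Dpt) followed at 1.94 (SE 0.51, adjusted p = 0.0159), a call lost without wild-type array 3 (adjusted p = 0.0864). Of 14 matrix proteases 6 rose, Adam12 fell by 0.23 on the log2 scale (adjusted p = 0.0445) and 7 did not pass, with the same 6 and 1 adjusted over the list alone (camera adjusted p = 0.000485, and adjusted p = 0.345 with an estimated correlation). The call of Adam12 ended without wild-type array 1 (adjusted p = 0.135) or 3 (0.142), Mdr2-KO array 1 (0.0873), 3 (0.0758) or 4 (0.0928), or Mdr2-KO/IL6-KO array 1 (0.0526), 3 (0.0549), 5 (0.0535) or 6 (0.0501), and after quantile normalization (0.203). Mmp12, the macrophage elastase, rose from 6.34 ± 0.32 to 8.40 ± 0.79 (2.05, SE 0.34, adjusted p = 0.000996). Monocyte and recruited macrophage markers rose in 6 of 19 and 13 did not pass, 6 rising when adjusted over the list alone (camera adjusted p = 0.00064, and adjusted p = 0.383 with an estimated correlation). Among them Gpnmb rose by 1.59 (SE 0.31, adjusted p = 0.00298), the tetraspanin Cd9 by 1.52 (SE 0.13, adjusted p = 4.31e-06) and Ccr2, the receptor that brings monocytes into tissue, by 1.06 (SE 0.15, adjusted p = 0.000358).

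**Figure D2:**
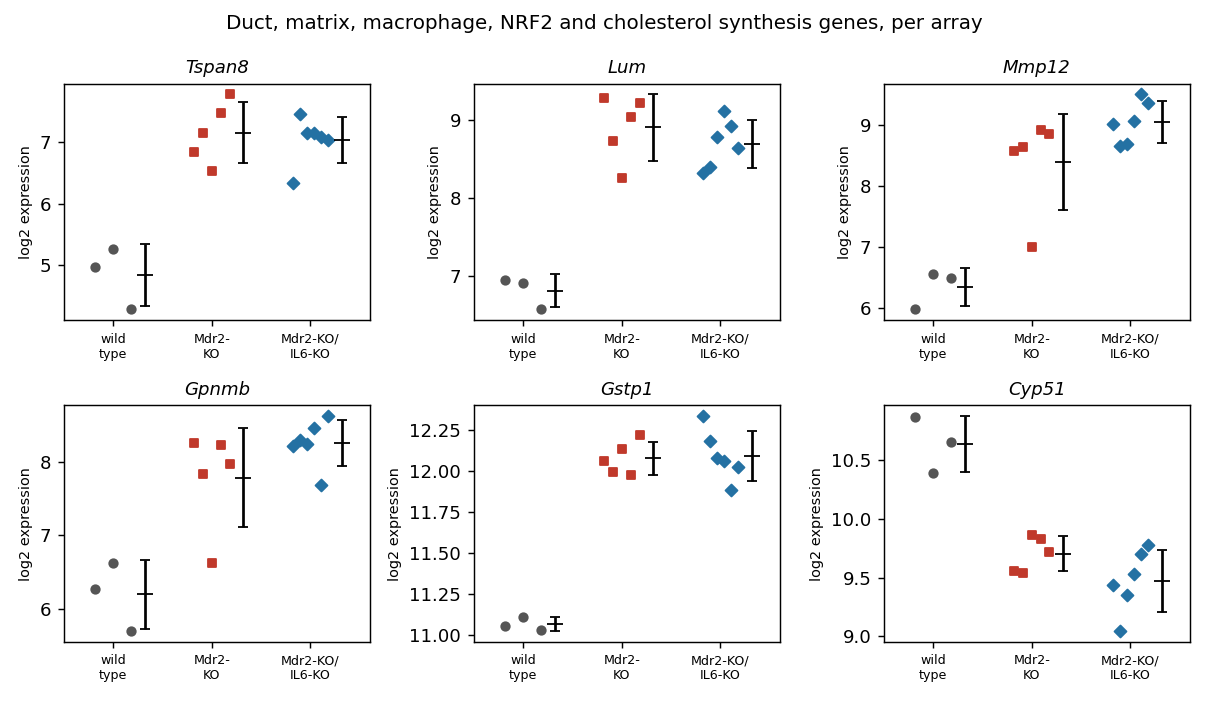
Log2 signal of genes of bile duct cells, matrix and macrophages, and of Gstp1 and Cyp51, in each array, by group, with black bars for the mean ± SD. Lumican rose from 6.81 ± 0.21 in wild type to 8.91 ± 0.43 in Mdr2-KO and 8.70 ± 0.31 in Mdr2-KO/IL6-KO, and Mmp12 from 6.34 ± 0.32 to 8.40 ± 0.79 and 9.05 ± 0.34.

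Female-biased liver genes had the largest list median, -2.91. Of 11 measured, 9 fell and the other 2 did not pass, and 9 fell when adjusted over the list alone (camera adjusted p = 0.00019, and adjusted p = 0.345 with an estimated correlation). The sulfotransferase Sult3a1 fell from 8.60 ± 1.83 to 3.51 ± 1.99 (-5.09, SE 0.88, adjusted p = 0.00139), with 7.06 in Mdr2-KO array 3 and 2.44 to 2.89 in the other 4 arrays. Cyp3a16 fell by 4.33 on the log2 scale (SE 0.90, adjusted p = 0.00428), and the Mdr2-KO means of Sult3a1 and Cyp3a16 are under the background, so the sizes of their falls are not exact. A1bg, which stayed above it, fell by 3.04 (SE 0.62, adjusted p = 0.00393). The groups overlapped for all 3 genes, through wild-type array 2. There Sult3a1 read 6.50 and Cyp3a16 4.95, under the background, beside 7.06 and 5.80 in Mdr2-KO array 3. A1bg read 7.66 in wild-type array 2 and 7.67 in Mdr2-KO array 4. Of 19 cholesterol synthesis genes 9 fell and 10 did not pass, 10 falling when adjusted over the list alone (camera adjusted p = 0.00353, and adjusted p = 0.659 with an estimated correlation). Lanosterol demethylase (Cyp51) fell from 10.64 ± 0.24 to 9.70 ± 0.15 (-0.93, SE 0.15, adjusted p = 0.000644), isopentenyl diphosphate isomerase (Idi1) by 0.76 and squalene epoxidase (Sqle) by 0.66. Cyp51 lies within 10 Mb of Abcb4, and an effect of donor-strain DNA around the targeted gene on its value was not excluded. Of 22 PPAR-alpha target and beta-oxidation genes 6 fell, Acadvl rose by 0.43 (adjusted p = 0.03) and 15 did not pass, with 7 falling and 1 rising when adjusted over the list alone (camera adjusted p = 0.0397, and adjusted p = 0.795 with an estimated correlation). Acadvl lost its call without wild-type array 2 (adjusted p = 0.101) or 3 (0.11) or Mdr2-KO array 4 (0.0623). The receptor gene Ppara itself fell by 0.82 on the log2 scale (SE 0.08, adjusted p = 2.5e-05) and Cyp4a31 by 1.45 (SE 0.34, adjusted p = 0.00883). The call of the PPAR-alpha list ended without any of wild-type arrays 1 (adjusted p = 0.101) and 2 (0.0571) and Mdr2-KO arrays 2 (0.0504), 3 (0.0658) and 5 (0.071).

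**Figure D3:**
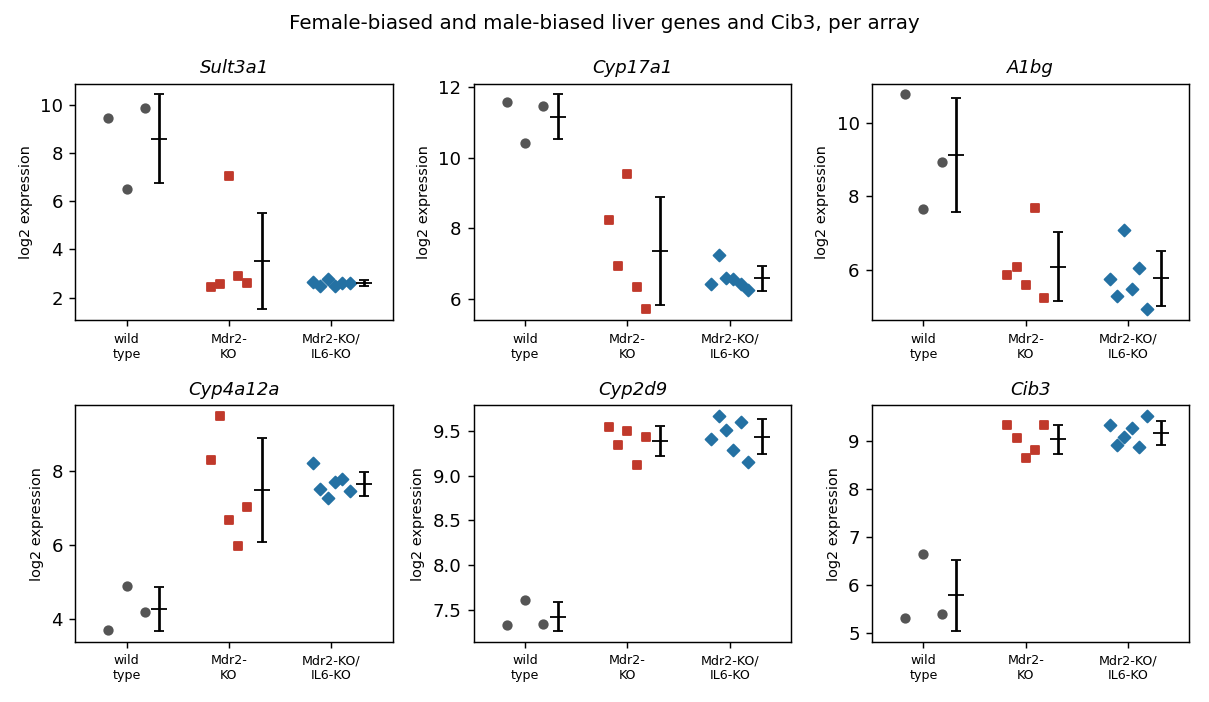
Log2 signal of sex-biased liver genes and of Cib3 in each array, by group, with black bars for the mean ± SD. Sult3a1 fell from 8.60 ± 1.83 in wild type to 3.51 ± 1.99 in Mdr2-KO and 2.6 ± 0.12 in Mdr2-KO/IL6-KO, both under the background, and Cyp17a1 from 11.17 ± 0.64 to 7.35 ± 1.54 and 6.59 ± 0.35.

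NRF2 target and glutathione genes rose in 6 of 15, Gclm fell by 0.41 on the log2 scale (adjusted p = 0.00771) and 8 did not pass, with 8 rising and 1 falling when adjusted over the list alone (camera adjusted p = 0.000419, and adjusted p = 0.383 with an estimated correlation). Glutathione S-transferase pi (Gstp1) rose from 11.07 ± 0.04 to 12.08 ± 0.10 (1.01, SE 0.09, adjusted p = 5.35e-06), and glutathione peroxidase 2 (Gpx2) by 1.14 (SE 0.24, adjusted p = 0.00429). Of 13 oncofetal and liver tumour genes 3 rose, Akr1c18 fell by 0.51 on the log2 scale under the background and 9 did not pass, with the same 3 and 1 adjusted over the list alone (camera adjusted p = 0.0157, and adjusted p = 0.446 with an estimated correlation). Those that rose were Ly6d, Tff3 and Golm1 (0.92), and without wild-type array 3 the list no longer passed (adjusted p = 0.0567). The fall of Akr1c18 (adjusted p = 0.0339) ended without wild-type array 2 (adjusted p = 0.0863) or 3 (0.13) or Mdr2-KO array 1 (0.0556), 4 (0.0593) or 5 (0.0648). YAP target genes rose in 3 of 9, among them Ankrd1 (1.10) and Ajuba (0.88), and 6 did not pass; 3 rose when adjusted over the list alone (camera adjusted p = 0.00565, and adjusted p = 0.644 with an estimated correlation). Heat shock genes rose in 4 of 11, led by Hspb1 (1.37) and Hsp90aa1 (0.71), and 7 did not pass, 4 rising when adjusted over the list alone (camera adjusted p = 0.00398, and adjusted p = 0.644 with an estimated correlation).

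Oxidative phosphorylation genes rose in 10 of 23, among them Ndufb8 (0.81, SE 0.13) and Uqcrfs1 (0.76, SE 0.11), while Uqcrc2 fell by 0.39 on the log2 scale (SE 0.06) and 12 did not pass. The same 10 and 1 passed when adjusted over the list alone (camera adjusted p = 0.000105, and adjusted p = 0.659 with an estimated correlation). Ribosomal protein genes rose in 10 of 20, among them Rpl7 (0.89, SE 0.14) and Rps14 (0.71, SE 0.10). Rps20 (-0.44), Rpl6 (-0.29) and Rpl4 (-0.26) fell, 7 did not pass, and 11 rose and 4 fell when adjusted over the list alone (camera adjusted p = 0.00262, and adjusted p = 0.659 with an estimated correlation). Rpl4 lost its call without wild-type array 1 (adjusted p = 0.0751) or 3 (0.0521) or Mdr2-KO array 1 (0.0544) and after quantile normalization (0.095), and so did Rpl6 after quantile normalization (0.0501). T cell markers fell in 5 of 13 and 8 did not pass, 8 falling when adjusted over the list alone (camera adjusted p = 0.00525, and adjusted p = 0.659 with an estimated correlation). The costimulatory receptor Icos fell by 0.45 on the log2 scale (SE 0.09, adjusted p = 0.00257) and the T cell list no longer passed without wild-type array 2 (adjusted p = 0.174). MHC class II and dendritic cell markers rose in 3 of 11 and 8 did not pass, with 3 rising and 1 falling when adjusted over the list alone (camera adjusted p = 0.0434, and adjusted p = 0.659 with an estimated correlation). H2-Ab1 led them at 1.0 (SE 0.27, adjusted p = 0.0174), a call lost without wild-type array 1 (adjusted p = 0.0682) or 3 (adjusted p = 0.118). The MHC class II list itself ended without wild-type array 1 (adjusted p = 0.193) or 3 (0.217) or Mdr2-KO array 1 (0.0834), 2 (0.0504) or 4 (0.0688), under quantile normalization (0.0742) and with only the 13292 brightest genes (0.182). In all, 15 of 46 lists moved, 11 up and 4 down, and the adjusted p of the other 31 lay between 0.0542 and 0.83.

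Small noncoding RNA genes, 53 of the 70 tested being small nucleolar RNAs, were singled out only after their values were seen. In Mdr2-KO 51 of the 70 were higher than in wild type and 1 was lower, with a median of 0.91. In Mdr2-KO/IL6-KO 30 of the 70 were higher than in wild type, the other 40 did not pass, and the median was 0.36.

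The comparison of Mdr2-KO/IL6-KO with wild type asks what the loss of both genes changes. Higher were 14 of 18 bile duct cell markers, 11 of 26 matrix genes, 8 of 14 matrix proteases, 8 of 19 macrophage markers and 10 of 15 NRF2 targets. With an estimated correlation these lists had adjusted p = 0.0928, 0.338, 0.0643, 0.0928 and 0.0653. Lower were 14 of 19 cholesterol synthesis genes, 6 of 18 fatty acid synthesis genes, 8 of 15 complement genes and 9 of 11 female-biased genes (adjusted p = 0.107, 0.345, 0.37 and 0.0492 with an estimated correlation). The macrophage elastase Mmp12 rose from 6.34 ± 0.32 to 9.05 ± 0.34 (2.71, SE 0.33, adjusted p = 0.000106), and Nqo1, the quinone reductase that NRF2 induces, from 7.25 ± 0.23 to 8.54 ± 0.21 (1.28, SE 0.16, adjusted p = 0.00012). Cyp51, which lies near Abcb4 as noted above, fell from 10.64 ± 0.24 to 9.47 ± 0.26 (-1.16, SE 0.14, adjusted p = 0.000106). In all, 2450 genes passed, 1388 higher and 1062 lower, and 748 changed at least 1.5-fold, 460 higher and 288 lower. With each array centred on its median the split was 1006 higher and 1573 lower.

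The largest rises from a mean signal above the background included Cib3 (3.40, SE 0.25, adjusted p = 9.2e-07), Ly6d (3.1) and Tff3 (2.95). Cyp4a12a, Cyp4a12b and Folh1 rose by 3.38, 3.29 and 2.88 from a wild-type signal under the background, so the sizes of these rises are not exact. Rragd, a GTPase that signals amino acid supply to mTORC1, rose from 5.60 to 8.34 (2.74, SE 0.15, adjusted p = 6.19e-08). The estrogen sulfotransferase Sult1e1 rose by 2.68 (adjusted p = 0.0128), a call lost without wild-type array 3 (adjusted p = 0.0805). The largest falls were Sult3a1 (8.60 ± 1.83 to 2.6 ± 0.12, -6.00, SE 0.86, adjusted p = 0.000374), Cyp3a16 (-4.71, SE 0.88, adjusted p = 0.00246) and Cyp17a1 (-4.58, SE 0.59, adjusted p = 0.000174). The transporter Slc22a26 fell from 11.23 to 8.38 (-2.86, SE 0.31, adjusted p = 4.3e-05). Cyp3a16 spread widely in wild type, at 8.58 ± 3.15, with 4.95 in wild-type array 2, under the background. In Mdr2-KO/IL6-KO Sult3a1 and Cyp3a16 were under the background, so the sizes of their falls are not exact.

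Cholangiocyte and ductular cell markers rose in 14 of 18 and 4 did not pass, 17 rising when adjusted over the list alone (camera adjusted p = 6.64e-14, and adjusted p = 0.0928 with an estimated correlation). Tspan8 rose by 2.18 (SE 0.27, adjusted p = 0.000114) from a wild-type signal under the background, Bicc1 by 1.49 (SE 0.21, adjusted p = 0.000312) and Krt19 by 1.16 (SE 0.22, adjusted p = 0.00285). Among 26 collagens and extracellular matrix genes 11 rose and 15 did not pass, 14 rising when adjusted over the list alone (camera adjusted p = 5.28e-08, and adjusted p = 0.338 with an estimated correlation). Lumican rose by 1.89 (SE 0.21, adjusted p = 4.57e-05) and thrombospondin 1 (Thbs1) by 0.79 (SE 0.17, adjusted p = 0.00579). Matrix proteases rose in 8 of 14 and 6 did not pass, 10 rising when adjusted over the list alone (camera adjusted p = 5.74e-07, and adjusted p = 0.0643 with an estimated correlation), with the gelatinase Mmp2 at 1.55 (SE 0.28, adjusted p = 0.00223). Of 19 monocyte and recruited macrophage markers 8 rose and 11 did not pass, 11 rising when adjusted over the list alone (camera adjusted p = 2.35e-06, and adjusted p = 0.0928 with an estimated correlation). Gpnmb rose from 6.19 ± 0.47 to 8.26 ± 0.32 (2.06, SE 0.30, adjusted p = 0.000471) and Cd9 by 1.62. YAP target genes rose in 6 of 9 and 3 did not pass, 7 rising when adjusted over the list alone (camera adjusted p = 6.76e-07, and adjusted p = 0.107 with an estimated correlation), with the matricellular protein gene Ccn1 at 1.44 (SE 0.23) and Ankrd1 at 1.52 (SE 0.25). Oncofetal and liver tumour genes rose in 6 of 13 and 7 did not pass, 7 rising when adjusted over the list alone (camera adjusted p = 2.18e-05, and adjusted p = 0.07 with an estimated correlation), with the fetal growth factor Igf2 at 1.87 (SE 0.40, adjusted p = 0.00574).

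NRF2 target and glutathione genes rose in 10 of 15 and 5 did not pass, 11 rising when adjusted over the list alone (camera adjusted p = 5.93e-08, and adjusted p = 0.0653 with an estimated correlation). Gpx2 rose by 1.5 (SE 0.23) and Gstp1 from 11.07 ± 0.04 to 12.10 ± 0.15 (1.03, SE 0.09). NF-kB target genes rose in 4 of 18 and 14 did not pass, 7 rising when adjusted over the list alone (camera adjusted p = 0.000409, and adjusted p = 0.338 with an estimated correlation), with the NF-kB subunit genes Nfkb2 at 0.60 (SE 0.07) and Relb at 0.38 (SE 0.07). Immediate early genes rose in 5 of 15 and 10 did not pass, 7 rising when adjusted over the list alone (camera adjusted p = 0.00124, and adjusted p = 0.496 with an estimated correlation). Klf6 led those that stayed past the threshold when any 1 array was left out (0.87, SE 0.15), whereas Jun (0.89, adjusted p = 0.0246) was lost without wild-type array 1 (adjusted p = 0.112) or 3 (adjusted p = 0.0886). Oxidative phosphorylation genes rose in 8 of 23 and 15 did not pass, 14 rising when adjusted over the list alone (camera adjusted p = 5.97e-07, and adjusted p = 0.37 with an estimated correlation), with Ndufa4 at 0.67 (SE 0.11). Ribosomal protein genes rose in 3 of 20, among them Rps14 (0.46, SE 0.10), and 17 did not pass, 10 rising when adjusted over the list alone (camera adjusted p = 0.000265, and adjusted p = 0.513 with an estimated correlation). The ribosomal list no longer passed without wild-type array 3 (adjusted p = 0.06).

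Cholesterol synthesis genes fell in 14 of 19 and 5 did not pass, 17 falling when adjusted over the list alone (camera adjusted p = 6.13e-12, and adjusted p = 0.107 with an estimated correlation). After Cyp51 came the sterol reductase Tm7sf2 (-0.94, SE 0.15) and Idi1 (-0.92, SE 0.14). Of 18 fatty acid synthesis genes 6 fell and 12 did not pass, 8 falling when adjusted over the list alone (camera adjusted p = 5.79e-06, and adjusted p = 0.345 with an estimated correlation), with acetyl-CoA carboxylase 2 (Acacb) at -1.23 (SE 0.23, adjusted p = 0.00247) and Pnpla3 at -0.92 (SE 0.14). Female-biased liver genes fell in 9 of 11 and 2 did not pass, 10 falling when adjusted over the list alone, with a median of -2.45 (camera adjusted p = 5.28e-08). With an estimated correlation this was the only list of the 3 comparisons to stay past the threshold, at adjusted p = 0.0492. Among 15 complement genes 8 fell and 7 did not pass, 9 falling when adjusted over the list alone (camera adjusted p = 0.000187, and adjusted p = 0.37 with an estimated correlation), with the mannose-binding lectin Mbl2 at -0.93 (SE 0.19, adjusted p = 0.00483) and Cfi at -0.42 (SE 0.09). Acute phase proteins fell in 7 of 26 and 19 did not pass, 9 falling when adjusted over the list alone (camera adjusted p = 0.00033, and adjusted p = 0.564 with an estimated correlation). The secreted hepatocyte protein Fgl1 fell from 11.94 ± 0.30 to 10.37 ± 0.31 (-1.57, SE 0.21, adjusted p = 0.000245) and serum amyloid A3 (Saa3) by 1.09 on the log2 scale (SE 0.21). In the PPAR-alpha list 2 of 22 fell, Ppara (-0.79, SE 0.08) and Cpt1a (-0.37, SE 0.09, lost without wild-type array 3 at adjusted p = 0.0549), and the same 2 passed when adjusted over the list alone (camera adjusted p = 0.00129, and adjusted p = 0.564 with an estimated correlation).

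T cell markers fell in 6 of 13 and 7 did not pass, 9 falling when adjusted over the list alone (camera adjusted p = 2.18e-05, and adjusted p = 0.37 with an estimated correlation). The T cell receptor subunit Cd3g, at -1.10 (SE 0.32, adjusted p = 0.0349), lost its call without wild-type array 2 (-0.71, adjusted p = 0.186), and so did Cd8b1, at -0.61 (-0.37 and adjusted p = 0.13 without that array). For Cd3g the call also ended without Mdr2-KO/IL6-KO array 1 (0.0517), 2 (0.0605), 3 (0.0579), 4 (0.051) or 6 (0.0526). NK and cytotoxic cell markers fell in 4 of 11 and 7 did not pass, 7 falling when adjusted over the list alone (camera adjusted p = 0.00246, and adjusted p = 0.235 with an estimated correlation). Granzyme A (Gzma) fell by 0.79 on the log2 scale to a level under the background, and Nkg7 by 1.0, or by 0.60 with adjusted p = 0.144 without wild-type array 2. B cell and plasma cell markers fell in 3 of 12 and 9 did not pass, 4 falling when adjusted over the list alone (camera adjusted p = 0.0441, and adjusted p = 0.554 with an estimated correlation). Cd79b, a B cell receptor subunit, fell by 0.78 on the log2 scale (adjusted p = 0.0298), a call lost without wild-type array 1 (adjusted p = 0.0817) or 2 (-0.48, adjusted p = 0.169) or Mdr2-KO/IL6-KO array 2 (adjusted p = 0.0557). The B cell list itself ended without Mdr2-KO array 3 and Mdr2-KO/IL6-KO array 2 together (adjusted p = 0.119), without wild-type array 2 (adjusted p = 0.345) or Mdr2-KO/IL6-KO array 2 (0.114), 3 (0.0507), 4 (0.0548) or 6 (0.0601), with centred arrays (0.0945) and with only the 13292 brightest genes (0.123).

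CAR and PXR xenobiotic metabolism genes went both ways, 7 of 16 falling, 3 rising and 6 not passing, with the same 7 and 3 adjusted over the list alone (camera adjusted p = 0.0312, and adjusted p = 0.469 with an estimated correlation). The drug-inducible cytochrome P450 Cyp2b10 fell from 9.21 ± 0.20 to 7.32 ± 0.55 (-1.89, SE 0.28, adjusted p = 0.000557). The list was lost without wild-type array 2 (adjusted p = 0.19) or Mdr2-KO/IL6-KO array 5 (0.0873), under quantile normalization (0.0999) and with centred arrays (0.0822). Interferon response genes fell in 5 of 20, led by the guanylate-binding protein Gbp3 (-1.02, SE 0.22), and 15 did not pass, 6 falling and 1 rising when adjusted over the list alone (camera adjusted p = 0.0317, and adjusted p = 0.616 with an estimated correlation). The interferon list was lost without wild-type array 1 (adjusted p = 0.138) or 2 (0.187) or Mdr2-KO/IL6-KO array 1 (0.0661) or 6 (0.108), without Mdr2-KO array 3 and Mdr2-KO/IL6-KO array 2 together (0.053), and with centred arrays (0.0822). Pericentral hepatocyte genes fell in 2 of 15 and 13 did not pass, the same 2 adjusted over the list alone (camera adjusted p = 0.0223, and adjusted p = 0.596 with an estimated correlation). They were the R-spondin receptor Lgr5 (-1.09, lost without wild-type array 3 at adjusted p = 0.072) and the glutamate transporter Slc1a2 (-0.85, lost without array 1 at adjusted p = 0.119 or array 3 at 0.109). The pericentral list was lost without wild-type array 1 (adjusted p = 0.213) or 3 (0.229) or Mdr2-KO/IL6-KO array 6 (0.0617), and with centred arrays (0.0522). In all, 23 of 46 lists moved, 11 up and 12 down, and the adjusted p of the other 23 lay between 0.104 and 0.757.

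**Figure D4:**
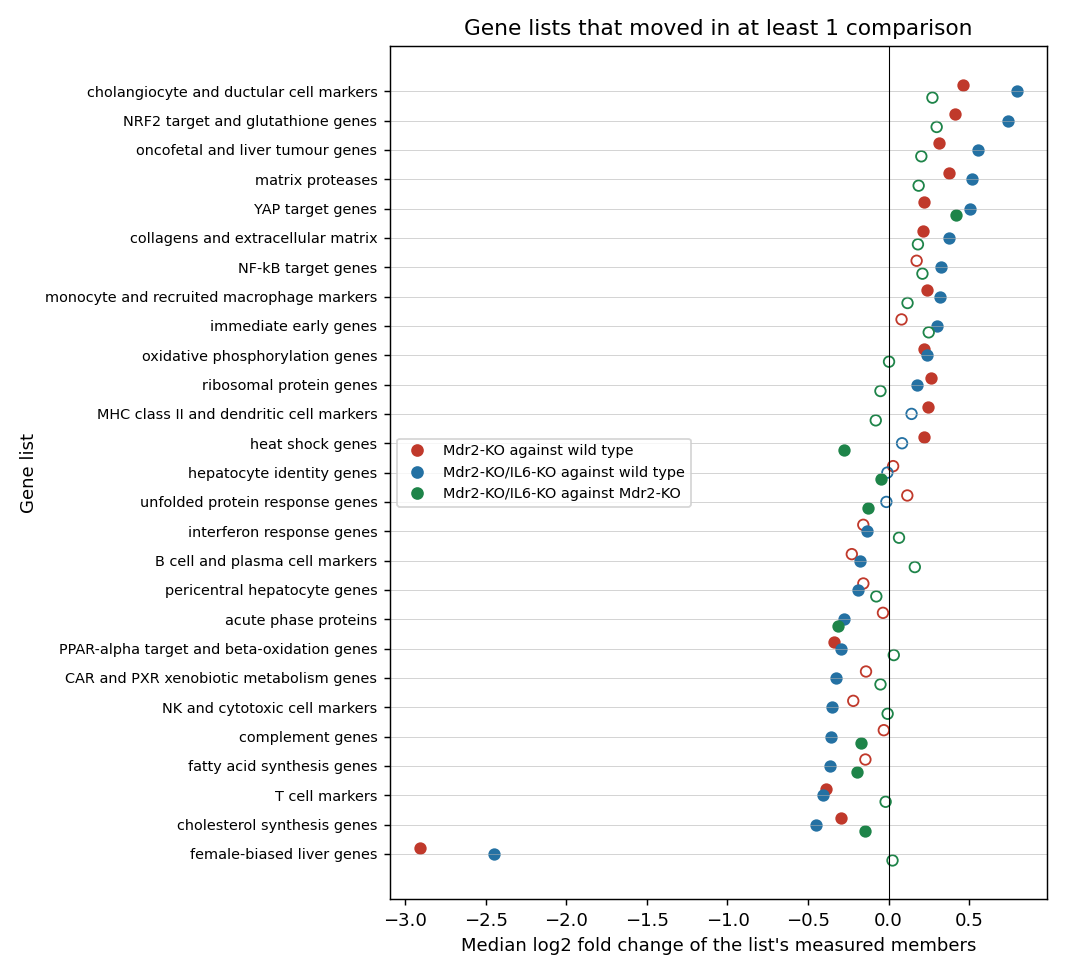
Each point is the median log2 fold change of a list's measured members in 1 comparison, filled where the camera adjusted p passed the threshold and open where it did not. Female-biased liver genes lie lowest, at -2.91 for Mdr2-KO and -2.45 for Mdr2-KO/IL6-KO against wild type.

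Both knockout groups were set side by side against the same wild-type arrays. Of the genes that passed, 902 were higher in both comparisons, where 123 would be higher in both if the calls were independent, and 698 were lower in both, against 129. Another 2 were higher in Mdr2-KO and lower in Mdr2-KO/IL6-KO, against wild type, and 0 the other way. These overlaps share the wild-type arrays, so chance alone adds to them, and they were not simulated. Fold changes of both knockout groups correlated across genes at r = 0.814. In 100 simulations of unchanged groups that share the wild-type arrays, r averaged 0.644 and ranged from 0.369 to 0.847, so this r is within what shared controls give. So is the share of genes with the same sign in both, 76.1%, beside 61.3% to 84.9% in the simulations. The covariance of the fold changes, 0.0729, was above the highest simulated value, 0.0202. As the simulated groups share the wild-type arrays too, with a mean covariance of 0.0107, these values argue against sharing as the whole of the covariance. With 3 wild-type arrays the controls cannot be divided into groups of 2, so the covariance was not measured with separate controls.

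The comparison of Mdr2-KO/IL6-KO with Mdr2-KO asks what loss of Il6 adds in liver that already lacks Abcb4. In Mdr2-KO/IL6-KO 10 of 26 acute phase genes and 3 of 15 complement genes were lower, with 1 complement gene higher, and neither list passed with an estimated correlation (adjusted p = 0.663 for each). Of 70 small noncoding RNA genes 40 were lower. Serum amyloid A1 (Saa1) fell from 8.04 ± 1.73 to 5.57 ± 0.44 (-2.47, SE 0.61, adjusted p = 0.0241), and without Mdr2-KO array 3, which read 11.12, it fell by 1.70 on the log2 scale (adjusted p = 0.0134). Wfdc21 fell from 10.07 ± 0.39 to 8.16 ± 0.81 (-1.90, SE 0.32, adjusted p = 0.00318). In all, 1746 genes passed, 1005 higher and 741 lower, and 150 changed at least 1.5-fold, 37 higher and 113 lower. The count was 754 without Mdr2-KO array 1, 932 without array 3, 999 without array 4, and 1055 and 1045 without Mdr2-KO/IL6-KO arrays 4 and 5, 970 without wild-type array 2 and Mdr2-KO array 3 together, and 687 without Mdr2-KO array 3 and Mdr2-KO/IL6-KO array 2 together. Which direction held more genes depended on the processing and on single arrays. There were 424 higher and 1056 lower when each array was centred on its median, 675 and 852 after quantile normalization, 1283 and 1661 with every probe tested, 360 and 394 without Mdr2-KO array 1, and 466 each way without array 3.

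Of 26 acute phase proteins 10 fell and the other 16 did not pass, and 12 fell when adjusted over the list alone (camera adjusted p = 2.03e-11, and adjusted p = 0.663 with an estimated correlation). The list median was -0.32, and -0.19 without Mdr2-KO array 3 (camera adjusted p = 1.12e-09). The acid glycoprotein Orm2 fell from 11.50 ± 0.77 to 10.30 ± 0.28 (-1.20, SE 0.28, adjusted p = 0.0196) and Fgl1 from 11.54 ± 0.41 to 10.37 ± 0.31 (-1.17, SE 0.18, adjusted p = 0.00225). Serum amyloid A2 (Saa2) fell by 2.08 on the log2 scale (SE 0.52, adjusted p = 0.0255), a call lost without Mdr2-KO/IL6-KO array 2 (adjusted p = 0.0508), and Saa3 by 0.98 (SE 0.18, adjusted p = 0.00484). Of 15 complement genes 3 fell, C8g rose by 0.38 (adjusted p = 0.00413) and 11 did not pass, with 4 falling and 1 rising when adjusted over the list alone (camera adjusted p = 7.96e-05, and adjusted p = 0.663 with an estimated correlation). C8a fell by 0.88 on the log2 scale (SE 0.20, adjusted p = 0.0142) and C4b by 0.43 (SE 0.11, adjusted p = 0.0254). Neutrophil markers were high in the array that was highest for acute phase genes. The list's mean relative to wild type was 2.66 in Mdr2-KO array 3 and -0.16 to -0.01 in the other 4, with S100a8, a calcium-binding protein abundant in neutrophils, at 10.12 against 6.16 to 6.71. The list was also high in Mdr2-KO/IL6-KO array 2, at 1.89 against -0.14 to 0.21. The neutrophil markers did not pass between the knockouts (camera adjusted p = 0.191) or with both arrays left out (0.859), but fell without Mdr2-KO/IL6-KO array 2 alone (adjusted p = 0.00601). That fall used the preset correlation and kept Mdr2-KO array 3. The estimated correlation of this list was 0.886, which gave camera adjusted p = 0.779 with all arrays. With both arrays left out the acute phase list had a median of -0.23 (camera adjusted p = 1.96e-11). The complement list had one of -0.08 (0.00286), beside -0.17 with all arrays. Saa2 (0.0586) and C8a (0.0519) lost their calls without both arrays. The STAT3 target list (camera adjusted p = 0.189) and the IL-6 family and receptor list (0.528) did not pass.

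**Figure D5:**
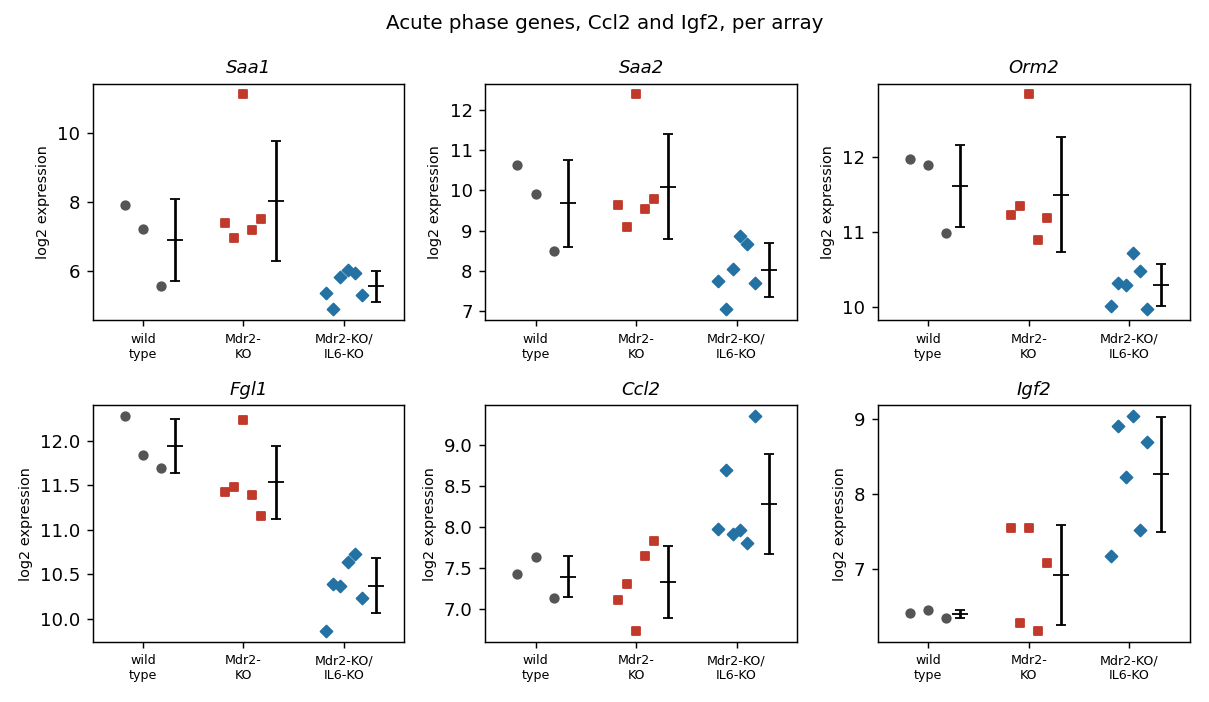
Log2 signal of acute phase genes, Ccl2 and Igf2 in each array, by group, with black bars for the mean ± SD. Orm2 fell from 11.50 ± 0.77 in Mdr2-KO to 10.30 ± 0.28 in Mdr2-KO/IL6-KO and Fgl1 from 11.54 ± 0.41 to 10.37 ± 0.31, and Mdr2-KO array 3 read highest for Saa1, at 11.12.

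Heat shock genes fell in 3 of 11 and 8 did not pass, 5 falling when adjusted over the list alone (camera adjusted p = 0.000115, and adjusted p = 0.663 with an estimated correlation), with the HSP70 co-chaperone Dnaja1 at -0.75 (SE 0.10, adjusted p = 0.00102). Cholesterol synthesis genes fell in 3 of 19 and 16 did not pass, 5 falling when adjusted over the list alone (camera adjusted p = 2.08e-05, and adjusted p = 0.663 with an estimated correlation). They included Dhcr7, which makes cholesterol from its last precursor (-0.45, adjusted p = 0.0101), and the sterol carrier Stard4 (-0.42, adjusted p = 0.00643). In the fatty acid synthesis list only Acacb fell of 18, by 0.76 on the log2 scale (adjusted p = 0.0282), and 17 did not pass; 1 fell when adjusted over the list alone (camera adjusted p = 6.05e-05, and adjusted p = 0.663 with an estimated correlation). That call of Acacb was lost without Mdr2-KO array 1 (adjusted p = 0.0543) or 3 (0.0681) or Mdr2-KO/IL6-KO array 2 (0.0534) or 6 (0.0531). In the hepatocyte identity list coagulation factor IX (F9) fell of 19, from 10.64 to 10.28 (-0.36, SE 0.07, adjusted p = 0.00458), and 18 did not pass, 2 falling when adjusted over the list alone (camera adjusted p = 0.0015, and adjusted p = 0.663 with an estimated correlation). After quantile normalization the hepatocyte list did not pass (adjusted p = 0.252).

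YAP target genes rose in 3 of 9 and 6 did not pass, 6 rising when adjusted over the list alone (camera adjusted p = 0.0214, and adjusted p = 0.684 with an estimated correlation). Ajuba rose by 0.46 (SE 0.12, adjusted p = 0.029), a call lost without Mdr2-KO array 1 (adjusted p = 0.0654) or 3 (0.0736) or Mdr2-KO/IL6-KO array 6 (0.0533). The YAP list no longer passed with wild-type array 2 and Mdr2-KO array 3 both left out (adjusted p = 0.0525), or with Mdr2-KO array 3 and Mdr2-KO/IL6-KO array 2 both left out (0.0871). Of 16 unfolded protein response genes the ER chaperone component Sdf2l1 fell by 0.63 on the log2 scale (adjusted p = 0.0146), the transcription factor Atf3 rose by 0.74 (adjusted p = 0.0396) and 14 did not pass, with 2 falling and 1 rising when adjusted over the list alone (camera adjusted p = 0.0228, down, and adjusted p = 0.663 with an estimated correlation). Atf3 was lost without wild-type array 1 (adjusted p = 0.0506), Mdr2-KO array 1 (0.0953), 2 (0.0601), 3 (0.0727) or 4 (0.0687), or Mdr2-KO/IL6-KO array 2 (0.0532) or 6 (0.0658), and with centred arrays (0.0585). Without Mdr2-KO array 3 and Mdr2-KO/IL6-KO array 2 Sdf2l1 was lost (0.0591). The unfolded protein response list was lost without Mdr2-KO array 3 (adjusted p = 0.0827), after quantile normalization (0.0938) and with only the 13292 brightest genes (0.0697). In all, 8 of 46 lists moved, 1 up and 7 down, and the adjusted p of the other 38 lay between 0.0662 and 0.867. Among those 38 were the female-biased genes, of which none of 11 passed (camera adjusted p = 0.291).

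The largest rises against Mdr2-KO included the splicing factor Phf5a (8.97 ± 0.11 to 9.92 ± 0.23, 0.95, SE 0.10, adjusted p = 0.00021), the actin regulator Cap2 (0.91, SE 0.14, adjusted p = 0.00243), Serpinb6a (0.89, SE 0.10, adjusted p = 0.000391) and the annexin partner S100a10 (10.95 to 11.74, 0.78, SE 0.09, adjusted p = 0.000398). The mRNA export factor Alyref rose by 0.76 (SE 0.09). Phf5a, S100a10 and Alyref had fallen in Mdr2-KO against wild type, by 1.38, 0.58 and 0.93 on the log2 scale. Among genes without overlap between the groups the transporter Slc4a9 rose most, by 1.35 (SE 0.37, adjusted p = 0.0344). Its call was lost without Mdr2-KO array 1 (adjusted p = 0.0634), 2 (0.0502), 3 (0.0831) or 4 (0.0671) or Mdr2-KO/IL6-KO array 2 (0.0555) or 6 (0.0533). Igf2 rose from 6.93 to 8.27 (1.34, SE 0.34, adjusted p = 0.0258), a call lost without Mdr2-KO array 4 (adjusted p = 0.0691) or Mdr2-KO/IL6-KO array 2 (0.0508) or 4 (0.0552). The heparan sulfate proteoglycan Gpc3 rose by 0.53 (SE 0.12, adjusted p = 0.0135).

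Small nucleolar RNA genes made up several of the largest falls against Mdr2-KO, with Rnu3a at -1.86 (SE 0.17, adjusted p = 8.43e-05), Snora16a at -1.58 (SE 0.16, adjusted p = 0.000193) and Snora3 at -1.56 (SE 0.15, adjusted p = 0.000128). Of the 53 small nucleolar RNA genes 30 were lower, none higher, and the median was -0.51. Of all 70 small noncoding RNA genes, the other classes included, 40 were lower, none higher, and the median was -0.48. Over the 58 of these 70 above the background, the mean of each array relative to wild type lay between 0.886 and 1.19 in Mdr2-KO, between 0.308 and 0.700 in Mdr2-KO/IL6-KO and between -0.134 and 0.0992 in wild type. The guanylate-binding protein Gbp11 fell by 1.22 on the log2 scale (SE 0.30, adjusted p = 0.0217), a call lost without Mdr2-KO array 1 (adjusted p = 0.0623) or 4 (0.0518), or without Mdr2-KO array 3 and Mdr2-KO/IL6-KO array 2 together (0.0513). Of the genes higher in Mdr2-KO than in wild type, 368 were lower in Mdr2-KO/IL6-KO than in Mdr2-KO, where 65.9 would be if the calls were independent, and of those lower in Mdr2-KO 499 were higher, against 122. These overlaps share the Mdr2-KO arrays, with opposite sign, so chance alone adds to them.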

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

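The tests of raised background, of sex, of hepatocyte share and of the male-biased list, and the small RNA class itself, were chosen after the result was seen; the other tests below were fixed before it.

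Single arrays were looked for in the 2 knockout groups, over 160 genes and 46 lists, which makes 412 groups of values. An array stood apart in 33 of them, where a gap test at the 95% level gives about 1 in 20 by chance, 20.6 here. The 3 wild-type arrays were too few for this test and were not examined. The female-biased list level was -0.76 in wild-type array 2, against 0.55 and 0.21 in the other arrays, relative to the wild-type mean. The value given is the gap to the nearest other array divided by the range of the group, given where it is past the critical value for that number of arrays. Mdr2-KO array 3 was the array apart in 16 genes and 3 lists. Its largest gap was in the mean level of the neutrophil list (0.9476, at 2.66 against -0.16 to -0.01 in the other arrays, relative to wild type). It was high for S100a8 (0.8599), Saa1 (0.8718, at 11.12 against 6.97 to 7.51 in the other arrays), Saa2 (0.7881), Orm2 (0.7617), C4b (0.865), Hp (0.7862), Stat3 (0.7652), Cd14 (0.7882), Mup3 (0.7129) and Sult3a1 (0.9042). It was low for Elovl7 (0.7971), Mmp12 (0.8206), Osbpl3 (0.7343), Gpnmb (0.7449), Cd2 (0.7945) and Trem2 (0.7514). In the same array the mean levels of the acute phase list (0.7479) and of the complement list (0.809) were high.

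Among the other Mdr2-KO arrays, array 1 was high for Mucl2 (0.7296) and low for Pnpla3 (0.8216), array 2 was low for Ndufa1 (0.8697) and array 5 was high for the B cell list (0.7591). In Mdr2-KO/IL6-KO, array 1 was low for Slc22a26 (0.7207) and high for Jun (0.669), array 2 was high for the neutrophil list (0.8243, at 1.89 against -0.14 to 0.21), S100a8 (0.8188) and Cyp17a1 (0.6594) and low for Mbl2 (0.7085) and the B cell list (0.6939), array 3 was high for Klra17 (0.7503) and Fcrl5 (0.8957), and array 4 was high for Cyp2b13 (0.7246).

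Small noncoding RNA genes were higher in all 5 Mdr2-KO arrays than in every other array. Relative to wild type, array means over 58 genes above the background were 0.886 to 1.19, against 0.308 to 0.700 in Mdr2-KO/IL6-KO. Camera on this class cannot serve as support, because the class was singled out for its values in these same arrays. For genomic DNA or a raised background in Mdr2-KO, olfactory receptor genes had a median log2 fold change of -0.108 against wild type and -0.0554 against Mdr2-KO/IL6-KO. The authors' background correction and quantile normalization can remove a raised background before this reading, so it cannot decide the question. DNase treatment of the RNA, per the labels, argues against genomic DNA. Handling or labelling that varied between arrays may still contribute, since within groups the small RNA level and the contrast of protein-coding genes that fell and rose had r = 0.0900 over 14 arrays (permutation p = 0.769, Spearman rho 0.262, p = 0.379, and r = 0.117 without the 2 farthest arrays), a relation too loosely measured to settle it. More transcription of the host genes is open too, as the 23 genes that hold 25 of the small RNAs had a median of 0.112 (95% interval 0.0147 to 0.361) beside 0.867 for those small RNAs, which leaves room for a part. A difference between the genotypes stays untested among the open explanations.

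Female-biased liver genes were lower in both knockouts, with list medians of -2.91 and -2.45 and 9 of 11 genes falling in each. By camera with an estimated correlation the list did not pass in Mdr2-KO (adjusted p = 0.345) and passed narrowly in Mdr2-KO/IL6-KO (adjusted p = 0.0492). The directional test of fry called the female-biased list lower in both (adjusted p = 0.000183 and 8.31e-05). Male livers among the knockout arrays are argued against by Xist, which was within 1 log2 unit of the wild-type mean in 11 of 11 knockout arrays, at 11.69 to 11.92, while the highest of 4 Y-linked genes read 4.84. A lower share of hepatocytes as the whole of the female-biased fall is argued against by hepatocyte identity genes in Mdr2-KO/IL6-KO against wild type. Their median was -0.0072 (95% interval -0.0936 to 0.0197), beside -2.45 for the female-biased list. A smaller loss of hepatocytes is not excluded, because normalization between arrays can hide it. In Mdr2-KO against wild type the median of hepatocyte identity genes was 0.028, and the question was not tested there. A shift of the whole male-biased programme the other way could not be told apart from single genes moving, as the tests of that list disagreed. Its camera adjusted p was 0.0655 in Mdr2-KO and 0.555 in Mdr2-KO/IL6-KO (0.644 and 0.818 with an estimated correlation), while fry called it higher in both (adjusted p = 0.0196 and 0.0238). Of its 12 genes 4 rose and 2 fell in Mdr2-KO, and 4 rose and 3 fell in Mdr2-KO/IL6-KO, with Cyp4a12a, Cyp4a12b and Cyp2d9 higher in both and Cyp7b1 lower in Mdr2-KO (lost without wild-type array 3, adjusted p = 0.106). A loss of sex-dependent hormone signalling in the knockouts was not tested.

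Changed genes near the targeted genes were counted because DNA of a donor strain can remain around a targeted gene. Within 10 Mb of Abcb4 (GRCm38.p6) the odds ratio for a gene changed at least 1.5-fold in both knockouts against wild type was 3.06 (95% interval 0.60 to 9.63, Fisher's exact p = 0.0838, 0.445 adjusted; 3 of 45 genes, 6.67% against 2.28% elsewhere). Those 3 were Abcb1b, Cacna2d1 and Cyp51, so this doubt bears on their values. Around Il6, for genes changed between the knockouts by any fold, it was 1.29 (0.80 to 2.005, Fisher's exact p = 0.266, 0.445 adjusted; 23 of 209 genes). These are 2 of 16 tests in 1 family, and neither interval excludes 1 or a raised share, so remaining donor DNA could not be told apart from its absence.

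A chance division of the arrays is argued against by the counts of changed genes, which were highest for the real division. Any systematic difference between the groups, a batch included, would also put the real division first. The real division gave 4189 genes for Mdr2-KO against wild type, the highest of 56 divisions, with 51 for the next (1 division as large, the real one). It gave 2450 for Mdr2-KO/IL6-KO against wild type, with 9 for the highest other of 84, and 1746 between the knockouts, with 8 for the highest other of 100 drawn.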

How the results depend on the processing

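Signal over background limits what could be read, as 29.2% of the genes had a mean under it, and among the 4189 genes changed in Mdr2-KO 575 were under it in both groups. No paired analysis was possible because the numbers in the titles are not shared between groups. A pseudocount was not varied because the table is already on the log2 scale. Leaving out wild-type array 2 with Mdr2-KO array 3, or Mdr2-KO array 3 with Mdr2-KO/IL6-KO array 2, and leaving out small RNA genes, were chosen after seeing the data; the cause was not tested for any change below, except where fewer arrays or a stricter threshold make it. Requiring at least a 1.5-fold change left 799, 748 and 150 genes, for Mdr2-KO and Mdr2-KO/IL6-KO against wild type and for the knockouts against each other. With a correlation estimated per list 0, 1 and 0 lists moved, the 1 being female-biased genes, and between the knockouts fry called 2 lists, neither of them among the 8. Between the knockouts, testing every probe gave 2944, leaving out the former pair of arrays gave 970 genes and the latter 687 (6 of the 8 lists and 42 of 79 gene calls kept), and centring each array moved 14 lists, 7 up and 7 down, the same 8 included, and quantile normalization 12, 7 up and 5 down, 6 of the 8 included. Leaving out each array in turn gave 2140 to 4507, 1635 to 2544 and 754 to 2164 genes, 13 to 18, 20 to 23 and 8 to 15 lists, and r from 0.784 to 0.844. The share of higher genes moved between the knockouts with every probe (1283 and 1661) and without Mdr2-KO array 1 (360 and 394), and it moved with scaling, for Mdr2-KO against wild type from 1772 higher and 2417 lower to 1793 and 1763 (quantile), between the knockouts from 1005 higher and 741 lower to 424 and 1056 (centred) or 675 and 852 (quantile), and for Mdr2-KO/IL6-KO against wild type from 1388 and 1062 to 1006 and 1573 (centred). The proliferation list, not moved in Mdr2-KO/IL6-KO against wild type (median -0.03, adjusted p = 0.646), ranged from -0.219 to 0.1326 over single arrays left out. Without wild-type array 2 it rose, at 0.1326 (adjusted p = 0.033), as it did, at the same 0.1326, with the former pair out. Counts stayed within 1.5 times under the other settings, at 3556, 2521 and 1527 genes with quantile normalization, 4203, 2579 and 1480 centred, 3705, 2627 and 1857 without the dimmest genes, 4398, 3119 and 2501 with array weights and 2899, 2018 and 2013 with only the 2 groups compared. Of the list members and named genes called, 99 of 168, 85 of 146 and 41 of 79 kept their call whichever array was left out, and so did 11 of 15, 18 of 23 and 7 of 8 lists. With fry 8 of 15, 16 of 23 and 0 of 8 lists kept theirs.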

Other observations

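The transporters of bile and blood-side export went both ways. Of 17 hepatobiliary transporters 3 rose and 4 fell in Mdr2-KO against wild type (camera adjusted p = 0.2), and 4 rose and 2 fell in Mdr2-KO/IL6-KO (camera adjusted p = 0.258). The multidrug transporter Abcb1b rose from 5.43 to 7.09 in Mdr2-KO (1.67, SE 0.15, adjusted p = 6.76e-06) and by 1.34 in Mdr2-KO/IL6-KO. Its wild-type signal is under the background, so these sizes are not exact, and it lies within 10 Mb of Abcb4, where an effect of donor-strain DNA was not excluded. Slc51b, which exports bile acids to the blood, rose by 1.61 in Mdr2-KO/IL6-KO. In Mdr2-KO it rose by 1.03, a call lost without wild-type array 1 (adjusted p = 0.0874) or 3 (adjusted p = 0.128). The export pump Abcc4 was higher in Mdr2-KO/IL6-KO than in Mdr2-KO by 0.79 (SE 0.20, adjusted p = 0.0248), a call lost without Mdr2-KO array 1 (adjusted p = 0.058).

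Lifr, a receptor chain for cytokines related to interleukin 6, fell by 0.98 on the log2 scale in Mdr2-KO (adjusted p = 0.002) and by 1.27 in Mdr2-KO/IL6-KO. Among male-biased genes, Cyp2d9 rose from 7.42 to 9.39 in Mdr2-KO (1.97, SE 0.12, adjusted p = 1.41e-07) and by 2.02 in Mdr2-KO/IL6-KO. The receptor gene Notch2 rose by 0.37 and 0.46 against wild type. Between the knockouts, the monocyte chemokine Ccl2 was higher in Mdr2-KO/IL6-KO (7.33 to 8.28, 0.96, SE 0.26, adjusted p = 0.0344). That call was lost without Mdr2-KO array 1 (adjusted p = 0.0851), 2 (0.05) or 3 (0.0864) or Mdr2-KO/IL6-KO array 2 (0.0658). The chemokine Ccl20 was higher by 0.47 (SE 0.11, adjusted p = 0.0152), a call lost without Mdr2-KO array 3 and Mdr2-KO/IL6-KO array 2 together (adjusted p = 0.0676). The proliferation list did not move in any of the 3 comparisons (camera adjusted p = 0.74, 0.646 and 0.226).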
